A study of Drosophila melanogaster with 5 samples.

How the data were processed

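Small RNA libraries were made from total RNA of dissected intestines and remaining carcasses of adult males. Per the labels, RNA was prepared in triplicate from both tissues, fragments of 18 to 29 nt were selected on gels, linkers were ligated to both ends, and libraries were sequenced on a NextSeq500. Per the submitters' processing notes, the tools were cutadapt 1.9.1, Bowtie2 2.3.2 and featureCounts, with Subread 2.0.0. The genome build, annotation release, strand setting and treatment of reads with several matches are not given in the sources used here. The deposited values were whole-number counts of reads per annotated mature microRNA arm, not normalised, with 1 column per library. The totals of 329424 to 3038873 are microRNA reads and not the full depth of a library. A count of 3 corresponds to 5.48, 8.14 and 9.11 CPM in the intestine libraries and 1.81 and 0.987 CPM in the carcass libraries, so rare microRNAs were measured more closely in the carcass.

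Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Only 2 carcass libraries are analysed here, in keeping with the 3 against 2 of the series design.

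The rows were matched to the BDGP6.54 annotation, 473 by name and 6 by synonym (miR-263a, bantam and let-7), and arms were assigned from their position in the hairpin. All coordinates are from that build, which was not compared with the authors' build, as the latter is not given. Near-identical copies (34 rows) can share reads and were treated as uncertain, as were antisense hairpins such as iab-4 and iab-8, since the strand setting is not known. Neighbouring hairpins on the same strand with gaps of at most 10000 bases were taken as one genomic cluster, so hairpins on opposite strands, such as mir-956 and mir-314, were not grouped.

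Counts were tested in R 4.3.3 with edgeR 4.0.16. Arms were kept by filterByExpr with the tissue as group (minimum count 10, minimum total 15), which left 222 arms holding 99.94 to 99.97% of the reads of each library. TMM factors were 0.87, 0.88 and 0.84 in the intestine and 1.28 and 1.21 in the carcass. The quasi-likelihood test compared the tissues without a replicate block, with a Benjamini-Hochberg adjusted p threshold of 0.05. Standard errors were computed as the absolute log2 fold change over the square root of the F statistic. Mean values are TMM-scaled CPM. For arms with no intestine read the fold is a lower bound set by 3 reads over the 3 libraries, and with 1 to 3 reads a ratio is given with its 95% exact counting interval.

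There were 14 lists fixed before the data were examined: microRNAs studied in the insect intestine, of muscle, of the nervous system and eye, of the testis clusters, of the ovary and early embryo, of the Hox clusters, of the let-7 Complex, of the mir-310 cluster, of the miR-2/13, miR-9 and miR-279 families, of the mir-317, mir-277 and mir-34 cluster, of metabolism, and mirtrons. Lists overlap: miR-8 and miR-277 are in the intestine and metabolism lists, miR-277 also in its cluster, let-7 in the intestine and let-7 lists, miR-9a in muscle and miR-9, miR-6, miR-286 and miR-4 in the ovary list and a family. Membership went by microRNA name, so both arms of a hairpin belong to a list, also in the families. Each list was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), beside an estimated correlation and fry. By fry, which asks only whether members move one way, its direction was opposite to that of camera for the Hox, metabolism and mir-317 lists.

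The text names, by a rule fixed before the data were examined, the 12 largest fold changes in each direction among called arms whose tissues did not overlap, the 5 smallest p in each direction, the 5 most abundant arms of each tissue, miR-958, and up to 4 called members of each list. Alternatives were RLE and upper-quartile factors, library totals with and without the most abundant microRNA, DESeq2 1.42.0, limma-voom, no filter, a mean of at least 10 CPM, a robust fit, a replicate block, a test against a 2-fold change, summed copies and leaving out each library. Without 1 carcass library, the lone one left is assumed to vary like the intestine libraries. Thinning of all libraries to the shallowest total was added after the totals were seen.

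The test was checked on counts simulated for the 222 arms, with 100 arms changed in each of 10 runs. It called 35.8% of arms changed 1.5-fold, 78.3% of those changed 2-fold and 99.4% of those changed 4-fold, and 2.32% of unchanged arms. With no change simulated, the median was 0 calls and the highest was 1 in 10 runs. The simulated changes were at most 4-fold and went up or down at random. In the data, 71 called arms were lower and 7 higher by at least 16-fold. The check therefore does not cover so uneven a difference, nor the dependence of the calls on the scaling.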

Results

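Small RNAs of 18 to 29 nt were sequenced from dissected intestines, and from the carcasses that remained, of adult Drosophila melanogaster males of the w1118 strain, a white-eyed laboratory stock, at 2 to 3 days of age. The carcass holds what is left once the intestine is removed, including muscle, nervous system, fat body, epidermis and testis. The deposited values were read counts for 479 mature microRNA arms of 259 hairpins in 3 intestine and 2 carcass libraries. The intestine libraries held 547937, 368352 and 329424 microRNA reads, and the carcass libraries held 1654625 and 3038873. The log2 CPM (read counts scaled to a common library size) of libraries of one tissue correlated across microRNAs with r between 0.982 and 0.993, against 0.705 to 0.719 between the tissues; microRNAs are not independent replicates. No library pair agreed within sampling noise, the closest being intestine 2 and 3 with a chi-square of 11.9 per degree of freedom, which gives no sign of a duplicated deposit but does not show that the libraries came from separate animals.

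The design asked which microRNAs differ between the intestine and the remaining carcass. The intestine was marked by miR-958, miR-956 and miR-314, with miR-10, miR-283 and miR-375 also higher. The carcass was marked by microRNAs of neurons and the eye (miR-124, miR-210, miR-263b), by the muscle microRNA miR-133, by miR-276b-3p and miR-993, and by the testis clusters. Of 222 arms tested, 77 were higher and 107 lower in the intestine at an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, n = 3 and 2 libraries). At least 4-fold differences were found for 29 of the higher and 85 of the lower arms. In 76 of the 77 higher arms and all 107 lower arms the values of the tissues did not overlap. The exception was miR-31b-5p, named here after its values were seen. Chance gives such separation for 20% of unselected arms. These arms were called on the same libraries, so their separation largely follows from the call and is not further evidence. The split depended on the scaling: with library totals in place of trimmed mean of M-values (TMM) factors, 50 arms were higher and 126 lower, so that 28.4% of the called arms were higher, against 41.8% with TMM. The median log2 fold change of all tested arms was -0.50 with TMM, -0.58 with upper-quartile factors, -0.72 with totals without the most abundant microRNA, -0.87 with RLE factors and -1.03 with totals. Small fold changes therefore depend on the scaling. These medians depend on which arms they cover and do not mark the level of no change. With TMM the median of the arms outside the testis clusters, a list with all tested arms lower, was 0.05, which does not mark it either.

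**Figure D1:**
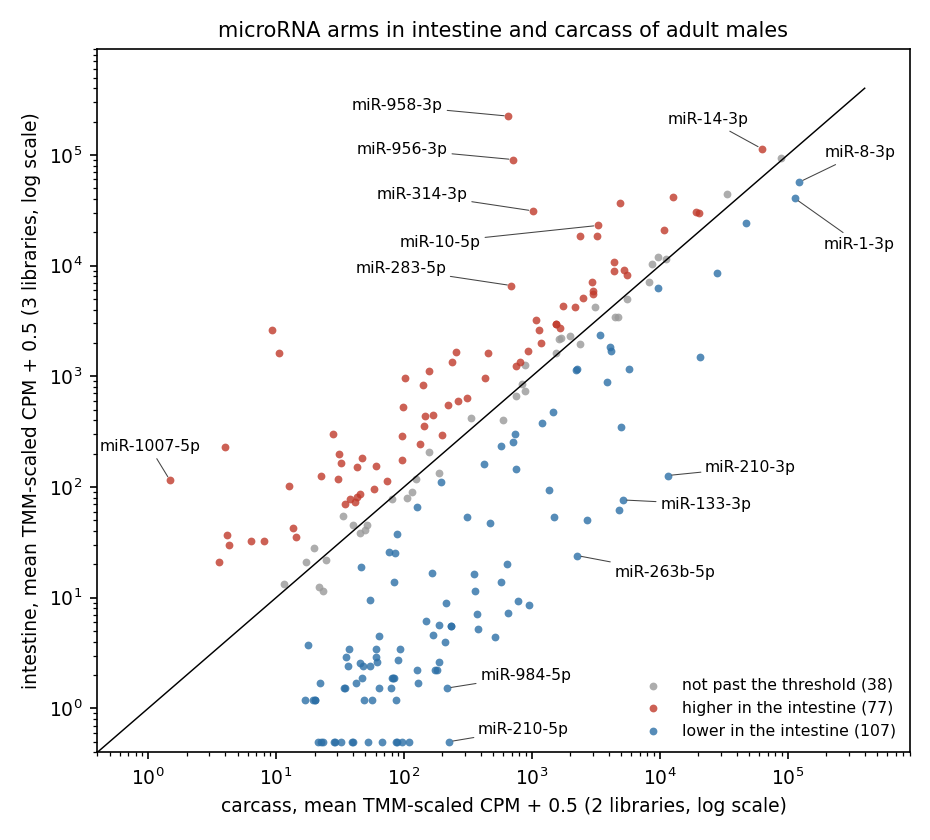
Mean TMM-scaled CPM plus 0.5 of each of the 222 tested arms in the carcass (2 libraries, x axis) and the intestine (3 libraries, y axis), both on log scales, with equal levels on the line. The 77 arms called higher in the intestine are red, the 107 called lower are blue and the 38 others are grey; miR-958-3p lies farthest above the line among the abundant arms, and the row of blue points at the bottom had no intestine read.

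miR-958, the microRNA that the study followed up, was the most abundant microRNA of the intestine. miR-958-3p measured 223876 ± 10330 TMM-scaled CPM in the intestine (SD, n = 3) and 654 ± 98.5 in the carcass (SD, n = 2). Its log2 fold change was 8.42 (SE 0.25, edgeR adjusted p = 1.76e-25), higher in 3 of 3 intestine libraries than in both carcass libraries, and lay between 7.90 and 8.57 over the other scalings, filters, tests and left-out libraries. The passenger arm, miR-958-5p, measured 2605 ± 365 and 8.88 ± 0.50 CPM, a log2 fold change of 8.17. In the BDGP6.54 annotation mir-958 (FBgn0262249) lies on the minus strand of chromosome 3L, at 22669289 to 22669380, with no protein-coding host gene, and miR-958-3p occupies 22669302 to 22669323.

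A pair of neighbouring hairpins on chromosome 3L, mir-956 and mir-314, was also higher in the intestine. miR-956-3p (11773740 to 11773762) measured 90726 ± 9126 CPM in the intestine and 713 ± 104 in the carcass, a log2 fold change of 6.99, and miR-956-5p had 7.26. miR-314-3p (11773081 to 11773101), encoded on the opposite strand, measured 31189 ± 5932 and 1019 ± 171 CPM, a log2 fold change of 4.94, and miR-314-5p had 6.08. Among arms hosted in introns of protein-coding genes on the same strand, miR-1007-5p in Abca3 had a log2 fold change of 6.91 but rested on 5 carcass reads. miR-283-5p in Gmap had 3.25, miR-1012-5p in Lerp 3.25, miR-4919-3p in Cyp4aa1 3.17 and miR-1006-5p in VhaSFD 3.02. miR-375-5p, from a hairpin on chromosome 2L with no protein-coding host gene, had 3.47. miR-4919-3p rested on 40 intestine and 24 carcass reads.

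The most abundant arms of the intestine were miR-958-3p, miR-14-3p, miR-34-5p, miR-956-3p and miR-8-3p, and those of the carcass were miR-8-3p, miR-1-3p, miR-34-5p, miR-14-3p and miR-276a-3p. miR-8-3p, a member of the miR-200 family, measured 56777 ± 1589 CPM in the intestine and 123164 ± 9053 in the carcass, a log2 fold change of -1.12. miR-276a-3p had -0.96 and was likewise called lower. miR-14-3p, known from cell death and fat metabolism, measured 113737 ± 18495 and 62693 ± 5781 CPM, a log2 fold change of 0.86 that was called with TMM but not with library totals (0.33) or DESeq2 (0.42). miR-34-5p measured 92986 ± 5710 and 88160 ± 18191 CPM and did not pass the test (log2 fold change 0.08, edgeR adjusted p = 0.689). Its sign turned with every other scaling, and with library totals it was called lower (-0.44).

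**Figure D2:**
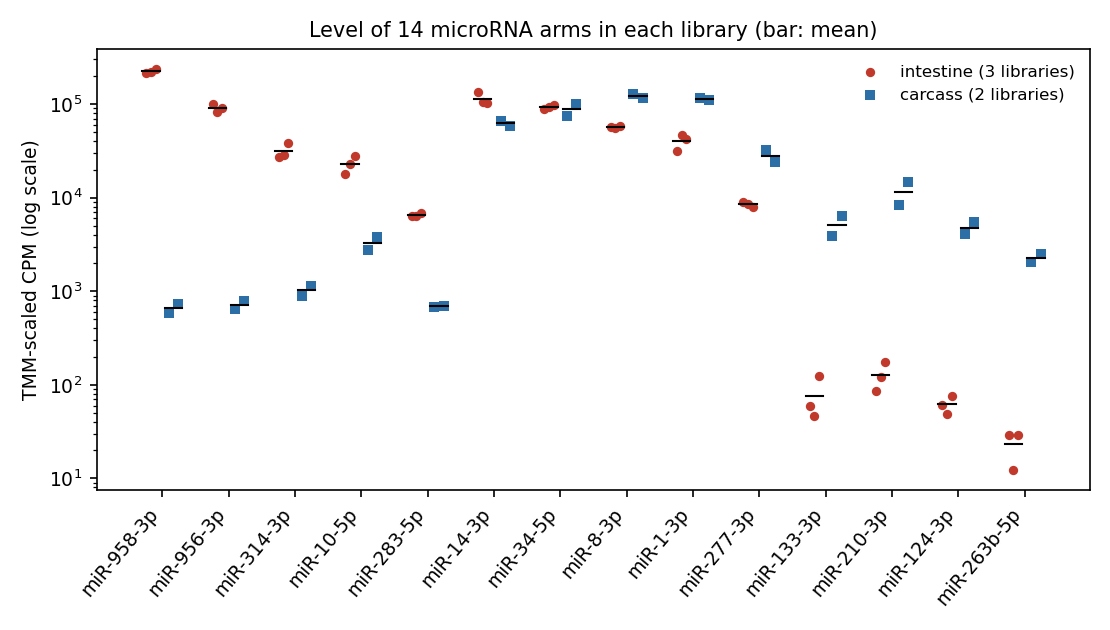
TMM-scaled CPM (log scale) of 14 arms in the 3 intestine libraries (red circles) and the 2 carcass libraries (blue squares), with bars at the means. The tissues overlap only for miR-34-5p; miR-958-3p averages 223876 CPM in the intestine against 654 in the carcass, and miR-210-3p averages 126 against 11505.

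Of the arms lower in the intestine, the 5 with the smallest p were miR-210-3p (log2 fold change -6.54), miR-124-3p (-6.28), miR-263b-5p (-6.55), miR-276b-3p (-5.80) and miR-133-3p (-6.12). miR-210-3p measured 126 ± 44.0 CPM in the intestine and 11505 ± 4477 in the carcass. miR-276b-3p measured 49.8 ± 13 and 2687 ± 214 CPM. Its 5p arm could not be judged, because miR-276b-5p had between 91.4 and 115.4% of the reads of miR-276a-5p in every library. There were 15 tested arms with no read in any intestine library, and their folds are lower bounds set by 3 reads summed over the 3 libraries. miR-210-5p was at least 85.0-fold lower in the intestine, miR-977-3p at least 39.0-fold, miR-2494-3p at least 35.2-fold, miR-985-3p at least 32.5-fold and miR-975-5p at least 30.3-fold. The mir-2494 hairpin lies in a coding exon of CG17560 on the same strand, and whether its reads are fragments of that transcript was not tested. The bounds were at least 23.6-fold for miR-960-3p, 19.4-fold for miR-983-2-3p, 15.1-fold for miR-969-5p, 13.8-fold for miR-2498-5p, 10.9-fold for miR-285-5p, 10.7-fold for miR-927-3p and 10.6-fold for miR-972-3p. Another 35 tested arms had 1 to 3 intestine reads. The intervals and bounds cover counting error only, since the reads carry no molecular identifiers.

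The testis clusters, groups of young microRNA genes known for expression in the male germline, were lower in the intestine throughout. All 34 tested arms were lower, over all arms tested and adjusted over the list alone. Their median log2 fold change was -5.54, or -4.86 with arms without intestine reads set at their bound. With 62 intestine reads over the list, nearly all of them passed the low-count filter only through the carcass libraries. The filter thus favoured this direction, so neither 34 of 34 nor the camera result is evidence about the list on its own. The list differed from the other arms by camera (adjusted p = 1.56e-07), but not with an estimated correlation (adjusted p = 0.0943). miR-963-5p had a log2 fold change of -5.30 and miR-978-3p -5.63. miR-962-5p had 2 intestine reads and was 94.3-fold lower (95% counting interval 26 to 780), and miR-984-5p had 1 read and was 243-fold lower (43.6 to 9622). Summed over all 42 arms of the list, tested or not, the intestine libraries held 62 reads. On library totals this was 1.34 ± 0.14% of the carcass level (SD, n = 3), a value that does not depend on the filter.

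MicroRNAs of the nervous system and eye were lower in the intestine in 9 of 10 tested arms, over all arms and adjusted over the list alone (median log2 fold change -5.18; camera adjusted p = 0.0219, and adjusted p = 0.390 with an estimated correlation). Besides miR-124, a microRNA of neurons, and miR-210 and miR-263b, miR-1000-5p was lower (-4.81). The exception was miR-137-3p, called higher at 1.18 and named here after its values were seen. On library totals the intestine level was 0.90 ± 0.17% of the carcass level for miR-124-3p, 0.77 ± 0.25% for miR-210-3p and 0.72 ± 0.29% for miR-263b-5p, against 157 ± 33% for miR-137-3p.

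The tested arms of the mir-310 cluster on chromosome 2R were all lower in the intestine, 8 of 8 over all arms and adjusted over the list alone. Their median log2 fold change was -4.49 (-4.37 at the bound). With 39 intestine reads over the list, they passed the low-count filter through the carcass libraries. The filter thus favoured this direction, so neither 8 of 8 nor the camera call is evidence about the list on its own. On pooled library totals, all 10 arms of the list, tested or not, summed to 31.3 CPM in the intestine and 1040 in the carcass. The hairpins mir-991 and mir-992 of the testis list lie in the same genomic cluster, so these list results are not fully separate. miR-310-3p had -4.46, miR-311-3p -4.80 and miR-312-3p -3.76, and miR-312-5p, with 2 intestine reads, was 44.0-fold lower (12.1 to 365). The camera call (adjusted p = 0.0332) was lost with an estimated correlation (adjusted p = 0.390), with RLE factors (0.0540), with library totals (0.05003), in thinned libraries (0.0624) and without carcass replicate 1 (0.0541); over all alternatives the adjusted p ran from 0.00458 to 0.390.

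The muscle microRNAs miR-1 and miR-133 were lower in the intestine to unequal degrees. miR-1-3p measured 40462 ± 7786 CPM in the intestine and 113769 ± 3071 in the carcass, a log2 fold change of -1.49, and miR-1-5p had -0.93. miR-133-3p measured 75.9 ± 41.1 and 5125 ± 1711 CPM, a log2 fold change of -6.12, and miR-133-5p, with 1 intestine read, was 24.2-fold lower (4.27 to 964). The intestine level on library totals was 24.7 ± 4.91% of the carcass level for miR-1-3p and 1.03 ± 0.53% for miR-133-3p. Of the 7 tested arms of the list, 4 were lower and 1 was higher, 5 passing when adjusted over the list alone; with RLE factors or library totals 6 were lower and 0 higher. The higher arm, miR-92b-3p (0.60), named here after its values were seen, was not called with any other scaling. The list did not differ from other arms (camera adjusted p = 0.486, and adjusted p = 0.768 with an estimated correlation).

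The miR-2/13 family list was higher in the intestine in 15 of 18 tested arms and lower in 2, with 17 passing when adjusted over the list alone. It holds both arms of each hairpin, so the 18 arms do not share a seed and the result is not about a seed family. The median log2 fold change was 0.97, against -0.93 for the other arms (camera adjusted p = 0.00449, and adjusted p = 0.390 with an estimated correlation). With library totals 8 arms were higher and 3 lower. miR-308-3p, in an intron of RpS23, had 2.83 and miR-2b-2-5p 1.84, and miR-308-5p was also higher. miR-13a-3p went the other way at -5.03, and so did miR-2c-5p, named here after its values were seen, with 2 intestine reads. Copies of miR-2a, miR-2b, miR-13b and miR-6 share reads, so the separate values of each copy are uncertain.

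Of the microRNAs studied in the insect intestine, 9 of 18 tested arms were higher and 8 lower, 17 passing when adjusted over the list alone. The list holds miR-958, chosen with knowledge of the study, so that member is not independent evidence. miR-263a-3p was higher (2.40), whereas miR-277-3p, known from the breakdown of branched-chain amino acids, was lower (-1.71). The list did not pass camera (adjusted p = 0.272, and adjusted p = 0.494 with an estimated correlation). It passed with the replicate block (0.0281), a fit in which intestine replicate 3 does not bear on the tissue difference. Its median, 0.35 with TMM, was below 0 with RLE factors (-0.01) and library totals (-0.17).

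In the cluster of mir-317, mir-277 and mir-34 on chromosome 3R, miR-277-3p and miR-277-5p (-1.30) were lower. miR-317-3p (0.56) and miR-317-5p (0.74) were called higher with TMM, but in 10 and 7 of 17 alternatives they were not. Neither was called with RLE factors, library totals or DESeq2, and miR-317-3p was not called without any 1 of the 3 intestine libraries, nor miR-317-5p without intestine replicate 1. The list's median was above 0 (0.15) with TMM and below it with RLE factors (-0.22) and library totals (-0.38), its mean below (-0.24) and its camera direction up (adjusted p = 0.748). The metabolism list had 4 arms higher and 5 lower of 10, 9 adjusted over the list alone. Its members miR-33-5p, in an intron of SREBP (1.30), and miR-14-5p (1.59) were higher. Its median (-0.44) and mean (-0.12) lay below 0, with a camera direction of up (adjusted p = 0.748). The Hox cluster list had 2 arms higher and 3 lower of 6, 5 adjusted over the list alone. miR-10-3p (2.96) and miR-10-5p (2.81) were higher, and miR-993-3p (-6.51) was lower. miR-993-5p, with 2 intestine reads, was 45.8-fold lower (12.6 to 379). Its median (-0.76) and mean (-1.28) were below 0, with a camera direction of up (adjusted p = 0.748). With an estimated correlation the adjusted p was 0.768 for these 3 lists.

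Of the microRNAs of the ovary and early embryo, not tissues of an adult male, only 3 of 20 arms were tested. All 3 were higher in the intestine, also adjusted over the list alone, at low levels. With carcass means of 3.80 (miR-286-3p), 3.09 (miR-6-1-3p) and 7.53 CPM (miR-5-5p), they passed the low-count filter only through the intestine libraries. The filter thus favoured this direction, and 3 of 3 is not evidence about the list. miR-286-3p had a log2 fold change of 2.97, miR-6-1-3p 2.68 and miR-5-5p 2.03, from 33, 23 and 34 intestine reads. The list missed the threshold (camera adjusted p = 0.0878, and adjusted p = 0.494 with an estimated correlation). It passed without the low-count filter (0.000917) and without intestine replicate 1 (0.0358), 2 (0.0125) or 3 (0.0189). Its camera adjusted p ran from 0.000917 to 0.494 over the 13 alternatives with a value for it, against 16 for each other list. The miR-279 family, which shares miR-286, had 4 of 5 arms higher, also adjusted over the list alone. They included miR-996-3p (1.04) and miR-996-5p (1.31), whereas miR-279-5p (0.92) was not called in 7 of 17 alternatives, among them RLE factors, library totals and leaving out intestine replicate 1 or 2. The arm not called was miR-279-3p (0.42, edgeR adjusted p = 0.0999), the more abundant arm of its hairpin, named here after its values were seen. The called miR-286-3p passed the filter only through the intestine libraries. The list had an adjusted p of 0.0612 by camera, passing without the filter (0.0279) and without intestine replicate 3 (0.0252), and 0.390 with an estimated correlation, within a range of 0.0252 to 0.390 over the alternatives.

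In the let-7 Complex, let-7-3p (1.35) and miR-100-3p (0.92) were called higher, 2 of 6 arms over all arms and adjusted over the list alone. Both are the less abundant arms of their hairpins. The more abundant arms let-7-5p (0.03), miR-100-5p (0.41) and miR-125-5p (0.27) were not called (edgeR adjusted p = 0.895, 0.111 and 0.252). The call of miR-100-3p was lost in 7 of 17 alternatives, among them RLE factors, library totals and leaving out intestine replicate 1 or 2. With library totals 1 arm of the list was higher and 1 lower (camera adjusted p = 0.208, and adjusted p = 0.451 with an estimated correlation). The miR-9 family had 3 of 8 arms higher with TMM, also adjusted over the list alone, but 2 higher and 3 lower with RLE factors (camera adjusted p = 0.298, and adjusted p = 0.716 with an estimated correlation). Those called with TMM were miR-79-5p (2.28), miR-9b-5p (0.76) and miR-9b-3p (1.32); miR-9b-5p was not called with RLE factors, library totals, DESeq2, no filter or thinned libraries, nor without intestine replicate 2 or 3, and miR-9b-3p was not called in 4 of 17 alternatives, among them library totals, DESeq2 and no filter. The mirtrons, made from short introns by splicing, had 6 arms higher and 5 lower of 16, 11 adjusted over the list alone, but 6 and 6 with RLE factors and 5 and 8 with library totals. miR-1007-5p, miR-1007-3p (2.67) and miR-1012-5p were higher, and miR-1015-3p in CG6432 (-5.82) was lower (camera adjusted p = 0.486, and adjusted p = 0.610 with an estimated correlation). The mirtron median was -0.14, or -0.50 with RLE factors and -0.66 with library totals, and its mean 0.01.

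**Figure D3:**
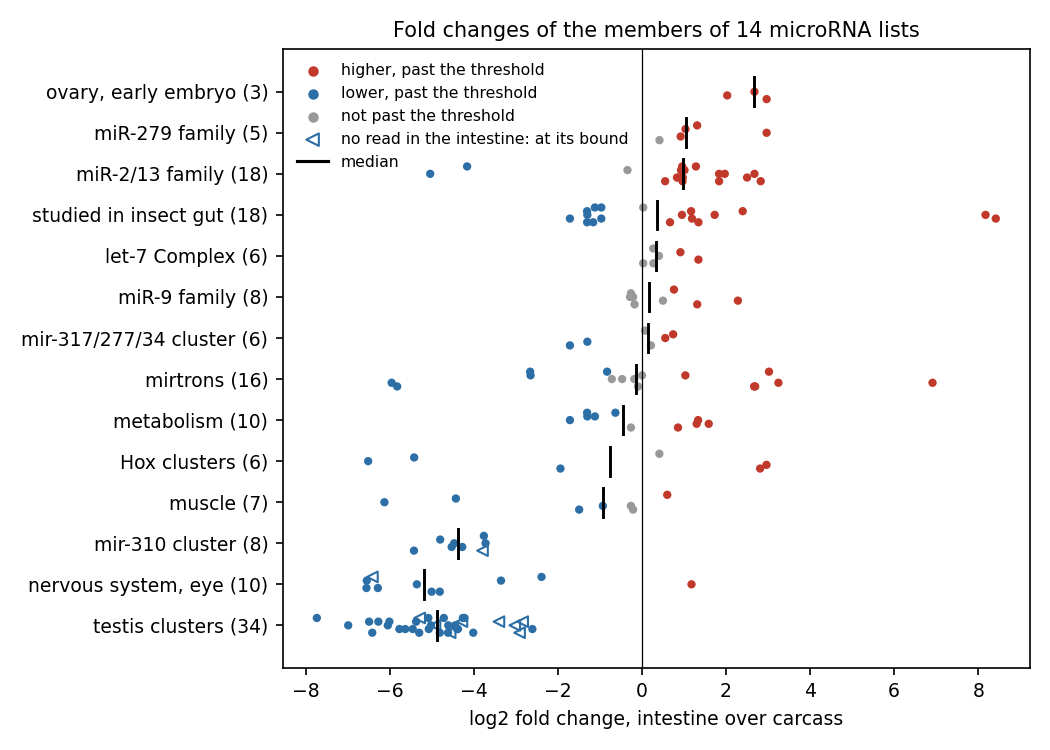
Log2 fold change, intestine over carcass, of the tested arms of 14 lists (number of arms in brackets), with red for arms called higher, blue for arms called lower, grey for others and a black bar at the median. Open triangles stand at the lower bound of arms with no intestine read; the 34 arms of the testis clusters all lie below 0, and the miR-2/13 family has a median of 0.97.

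A few microRNAs held most of the reads in both tissues. The 10 most abundant arms held 67.0 ± 0.27% of microRNA reads in the intestine (SD, n = 3) and 69.1 ± 2.04% in the carcass (SD, n = 2), a difference of -2.09 percentage points. The exact two-sided permutation test over the 10 assignments of the libraries gave p = 0.1, the smallest it can give, so the design could not reach 0.05. The difference was -0.655 points without carcass replicate 1 and -3.53 without carcass replicate 2, and the intestine had the larger share for the single most abundant arm (19.3 against 15.3%) and for the top 20 (84.1 against 81.0%).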

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

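The count of called microRNAs, 184 with TMM, lay between 134 and 206 over the alternatives, of which thinning was chosen after the totals were seen. No arm called in one direction was called in the other in any of them. The count higher in the intestine fell from 77 to 50 with library totals and to 41 in the test against a 2-fold change, which by construction calls fewer arms. The first follows the scaling: without the TMM factors the median log2 fold change moved by -0.52, from -0.50 to -1.03. Which scaling lies closer to the true levels was not tested. Of 14 lists, 4 passed camera, 0 with an estimated correlation and 9 by fry, which does not compare a list with other arms. The top-10 share difference of -2.09 points turned to 4.004 for the single most abundant arm and 3.10 for the top 20, and lay between -3.53 and -0.655 when libraries were left out; the cause was not tested.

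The log2 fold change of miR-34-5p (0.08, not called) turned to -0.28 with RLE factors, -0.012 with upper-quartile factors, -0.44 with totals, -0.13 with totals without the most abundant microRNA, -0.36 with DESeq2, -0.33 without the filter, -0.18 with a mean of at least 10 CPM and -0.14 in thinned libraries. It lay between -0.21 and 0.29 when each library was left out, below 0 in 4 of 5 fits. List values are the list mean minus that of other arms in log2 fold change, a measure that replaced a signed p after the first values were seen. For the muscle list it turned to 0.35 without intestine replicate 1 and 0.0045 without replicate 2, in a range of -0.72 to 0.35 over left-out libraries. The Hox list's turned to -0.0053 with limma-voom and -0.19 without intestine replicate 2, in a range of -0.19 to 0.41. Neither list passed camera in any setting, and the cause was not tested. Named arms lost a call in 44 other cases, all of them among miR-14-3p, miR-317, miR-100-3p, miR-9b and miR-279-5p.

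The labels do not say whether replicate numbers pair the samples. Libraries with the 2 shared numbers had correlations of 0.026 and 0.021 between their deviations from the tissue means. With 2 carcass libraries these deviations are mirror images of each other, so the check cannot tell whether the samples are paired. Replicate 3 has no carcass library, so with the replicate block intestine replicate 3 did not bear on the tissue difference. In that fit 180 arms were called, 73 higher and 107 lower, 5 lists passed, miR-958-3p had 8.39, and miR-9b-3p (1.33) was not called. The intestine list then passed (adjusted p = 0.0281, within 0.0281 to 0.494 over its alternatives). A robust fit does not enter camera, DESeq2 was not run for lists, and the pseudocount alternative did not apply to counts. For the 15 tested arms with no intestine read, the depth of the intestine libraries allows only lower bounds on the fold.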

Other observations

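All tests in this part were chosen after the data were seen, except 2 of the minor-arm tests, which were written down before their results.

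The 2 arms of a hairpin differed unequally between the tissues in 18 of 85 hairpins tested for arm usage (edgeR, adjusted p under the threshold). The count was between 14 and 20 without 1 of the intestine libraries, with 13 to 15 of the 18 called again. Without a carcass library it was 14 or 16, in fits that assume that the lone carcass library varies like the intestine libraries. The less abundant arm was relatively higher in the intestine in 13 and lower in 5. Of the 18 hairpins, 15 were single-copy. The others, mir-2a-1, mir-2b-2 and mir-13b-2, are all among the 13, and their copies can share reads. The smallest p belonged to mir-276b, among the 5, whose difference shared reads of the 5p arm may account for. miR-184-5p had a log2 fold change of 2.57 against 0.41 for miR-184-3p, and miR-92a-3p had 2.00 against -0.55 for miR-92a-5p. In mir-284 the 3p arm had -1.67 and the 5p arm 0.00. The ratio of miR-1-3p to miR-133-3p reads was 636 ± 347 in the intestine (SD, n = 3) and 23.6 ± 8.48 in the carcass (SD, n = 2). In the reverse direction, the carcass libraries held miR-958-3p at 0.385 and 0.453% of the intestine level and miR-314-3p at 4.26 and 5.13%.

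Minor arms appeared to make up a larger share of their hairpin in the intestine, but no overall shift was shown. The first comparison kept hairpins with at least 20 minor-arm reads in every library and found a higher share in 28 of 35, a median log2 difference of 0.454 (exact permutation p of library medians 0.2); because a minimum in every library selects on the outcome, it was replaced after those results were seen by a mean of at least 20 in thinned libraries, with 31 of 43, a median of 0.407 and p = 0.5, or 67 of 88, 0.508 and p = 0.1, the smallest possible, without thinning. With the first rule the median was 0.454 for single-copy hairpins (24 of 29), 0.225 after thinning for depth (20 of 27) and 0.516 for hairpins with less abundant major arms (12 of 17). With the mean rule they were 0.407 (27 of 37), 0.407 (31 of 43) and 0.424 (14 of 21), so the agreement of 75% of hairpins that each test required was met only for single-copy hairpins with the first rule, which argues against shared copies there but not with the mean rule, and shared copies, depth and abundant major arms all stay open. For mir-276b alone, shared reads may account for the arm difference. In the intestine miR-276b-5p had 99.9 ± 13.4% of the reads of miR-276a-5p (SD, n = 3). There miR-276b-3p had 0.212 ± 0.073% of those of miR-276a-3p.

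MicroRNAs of carcass tissues had reads in the intestine libraries. A single carry-over of carcass RNA, or misassigned reads, would bring all of them at one ratio. miR-1-3p, at 19.6% of the carcass level in its lowest intestine library, was above the upper bound for miR-133-3p in all 3 libraries, and miR-137-3p was at 125% in its lowest, which argues against it as the source of these. For miR-124-3p, miR-210-3p, miR-133-3p, miR-263b-5p and the testis clusters the highest mean ratio was 1.86 times the lowest, as one carry-over of about that size could give. The members were picked with their rough ratios already known. Of other arms lower in the intestine, miR-993-3p and miR-276b-3p lay within these ratios, but miR-1000-5p and the mir-310 cluster lay above them. The closeness thus holds for the chosen members only, and low expression in the intestine was not tested and stays open.

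Hairpins of one genomic cluster may share their tissue difference. The test covered 53 hairpins in 16 clusters of the same strand, which leave out mir-956 and mir-314. Their mean absolute difference in log2 fold change within clusters was 1.59. In 10000 random draws of 53 values from 125 single-copy hairpins, clustered or not, the median was 4.12 (permutation p = 1e-04, the smallest they can give). The test was chosen after the testis and mir-310 calls had been seen. Without the testis list the difference within clusters was 1.07 against 3.74. The mir-310 cluster, also seen beforehand, was still included, except for mir-991 and mir-992, which lie in it and belong to the testis list. The fitted values of arms with few intestine reads depend on the prior count, and no technical explanation was tested. miR-283-5p stood apart from its neighbours miR-12-5p (0.31) and miR-304-5p (-0.16), and miR-13a-3p from miR-2c-3p (-0.34).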
